A study of Mus with 4 samples.

How the data were processed

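Bone marrow of 4 mice was profiled by 10x Genomics single-cell RNA sequencing, 2 mice at 2 months and 2 at 6 months after transplant. Per the labels, the cells of both mice of a time were pooled in a library and hashtag oligos mark the individual mouse. The values used are raw UMI counts per gene and per tag: per the submitters' processing notes, Cell Ranger 5.0.1 with genome mm10 made the counts before they were deposited, and the barcode lists are those the authors' run called as cells. Seurat is also named in those notes, and the deposited counts are whole numbers with no normalization. Separate matrices of hashtag counts cover 6794880 barcodes in a library. They matched the tag counts of all 18971 and 16156 cell barcodes once bases 8 and 9 of each barcode were complemented, and 78.8% and 81.8% of their counts lay in called cells. Each matrix holds 32285 genes and 20 tags. Tags HTO_M0301 and HTO_M0302 made up the 2 month library and HTO_M0303 and HTO_M0304 the 6 month library. The sources used here do not say which tag is which mouse, so mice are numbered by tag.

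Barcodes with at least 500 UMIs, 200 genes and at most 10% mitochondrial UMIs were kept (16262 and 14766); 2708 and 1390 barcodes exceeded the mitochondrial limit. A cell was given to a mouse where a Gaussian mixture of 2 components on log10 tag counts called exactly 1 of the library's tags. Cells with both tags (1330, 8.18%, and 947, 6.41%) and doublets called by Scrublet (1258, 7.74%, and 850, 5.76%, at thresholds of 0.393 and 0.349) were removed. Scrublet called 38.9% and 41.1% of the cells with both tags and 4.15% and 3.06% of those with 1. A further 1454 and 380 cells had no tag and entered the clustering only.

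Clustering used scanpy 1.11.5 and leidenalg 0.10.2 under Python 3.11.15, with 2000 variable genes (1951 after sex-linked marker genes, mitochondrial genes and antibody and T cell receptor genes were left out), 30 principal components, 20 neighbours and Leiden resolution 1. A first clustering split by library, so the libraries were balanced, a choice made after seeing the data. Each variable gene was centred and scaled within each library before the principal components, and the graph took equal neighbours from both libraries. The centring also takes mean differences between the libraries out of the clustering, whatever their source. A cluster was named where at least 3 fixed markers of a class were among its 50 leading genes, taken from genes in at least 20% of its cells, and its 10 leading genes held no more markers of another class. Of 26 clusters 24 were joined into 12 classes, and clusters 13 and 3 stayed unnamed.

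Counts were summed per mouse and class and tested with edgeR 4.0.16 under R 4.3.3, by quasi-likelihood with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment within a class at 0.05, in classes with at least 20 cells in every mouse. Class shares were tested with edgeR on cell numbers. For 23 gene lists, camera of limma 3.58.1 was run on the edgeR fit with a preset correlation of 0.01 between genes, adjusted over all list and class pairs with at least 5 tested genes. The donor sex list had too few tested genes in every class; Xist stood at 1333, 1243, 1094 and 966 CPM in the 4 mice, and Ddx3y and Eif2s3y had 0 UMIs. CPM were computed here from the deposited counts with the edgeR library sizes. Standard errors of log2 changes come from the edgeR F statistic. Positions are from the GRCm38.p6 annotation, matched by symbol for 14579 of 15606 tested genes. The counting could split reads between near-identical copies, so immunoglobulin segments, histone genes and ribosomal protein genes are uncertain.

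Lists, markers, tests and the rule for named genes were set before the data were examined. The rule takes, among changed genes with a mean of at least 20 CPM and no overlap between the mice of the times, the 5 largest rises and falls in a class (10 in megakaryocytes and whole marrow), leaving out predicted genes and immunoglobulin and T cell receptor segments. It adds Il4, Il13, Il4ra, Il13ra1, Jak2, Tgfb1, Tgfbr1 and Tgfbr2, and up to 4 members of each passing list with the smallest p. The rule named 182 genes, and the text gives a part of them. Shares of cells with a UMI carry exact 95% intervals and Fisher's exact test within a library, which describes that library. The limit that a count of 0 allows is 3 divided by the number of cells.

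The gene test was tested on simulated counts with 200 changed genes. At log2 changes of 0.5, 1 and 2 it called 33 of 67, 58 of 67 and 64 of 66 in granulocyte-monocyte progenitors, 4 of 67, 44 of 66 and 63 of 65 in basophils, 4 of 66, 40 of 67 and 62 of 65 in megakaryocytes and 0 of 67, 19 of 66 and 53 of 66 in whole marrow. False calls were 10 of 11807, 2 of 8775, 4 of 10274 and 4 of 15180. Of 10 simulated lists shifted by 0.5, 10 were called in each, and of 10 unshifted lists 0, 0, 1 and 0. The counts were drawn with each gene's dispersion on the fitted trend, independently between genes and with no library effect. With spread around that trend the shares called may be lower in the data. Because simulated genes were independent, the simulated lists do not test the preset correlation.

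The alternatives set in advance were a stricter hashtag call (leading tag at least 90% of the counts and 20 counts), a stricter cell filter (1000 UMIs, 500 genes, 5% mitochondrial), Scrublet doublets kept, Leiden resolution 2, TMM scaling of cell numbers, relative log expression, DESeq2 1.42.0, no filter on low counts, cells thinned to at most 1000 UMIs, camera with an estimated correlation, fry, lists without the top 50 genes of free RNA, and leaving out each mouse. Free RNA was profiled from called barcodes without a tag and with under 1000 UMIs (1275 and 260 barcodes), since barcodes outside cells carry only tag counts in the files. These barcodes may include damaged cells, so the profile may not be free RNA alone. Since balancing was chosen after seeing the data, the first, unbalanced clustering was added as an alternative, and so were class totals without cluster 3 and lists within the shortest of 4 sets of genes by span, both also chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.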

Results

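Single-cell gene expression was measured in bone marrow of mice that had been transplanted with Vav-Cre+ cells carrying a mutant Jak2 allele, a mouse model of myeloproliferative neoplasm. Marrow was taken 2 months or 6 months after the transplant. At each time the cells of 2 mice were pooled into 1 10x Genomics library, and hashtag oligos marked the mouse of origin, which is the replicate here (n = 2 mice per time, 4 in all). The deposited files held UMI counts, which are counts of distinct captured transcripts, for 18971 barcodes at 2 months and 16156 at 6 months. After filtering, 12737 and 12978 cells carried the tag of a single mouse. The mice contributed 6720 and 6017 cells at 2 months and 5546 and 7432 cells at 6 months, with totals of 130018659, 158352344, 138824791 and 203156079 UMIs and medians of 18545.5, 23997, 22501.5 and 23005.5 UMIs per cell. Cells fell into 26 clusters, and 12 classes were named from fixed markers. Each class name stands for cells like that type, as judged by those markers. HSPC denotes haematopoietic stem and progenitor cells.

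The series concerns IL-13 and IL-4, cytokines of type 2 immunity, in the progression of the disease to marrow fibrosis, so the first question was which marrow cells held their transcripts. With the mice of a library pooled, most cells with Il4 were basophils. An Il4 UMI was found in 63 of 399 basophils at 2 months (15.8%, exact 95% interval 12.4 to 19.7) and in 80 of 527 at 6 months (15.2%, 12.2 to 18.5). These cells made up 52.9% and 71.4% of all cells with Il4, and held 75 of 156 Il4 UMIs at 2 months and 92 of 126 at 6 months; at 2 months megakaryocytes held 34 and erythroid cells 19. The share of basophils with Il4 was 13.9% and 19.3% in the mice at 2 months and 14.8% and 15.4% in those at 6 months. In mouse 2 of 2 months basophils were the largest class with Il4 but not most of these cells. There 27 basophils held it, against 17 erythroid cells, 8 megakaryocytes and 6 cells of the unnamed cluster 13. Il13 was rare. It was seen in 1 of 399 basophils at 2 months (0.251%) and in 8 of 527 at 6 months (1.52%, 0.658 to 2.97), 5 of them from mouse 1 and 3 from mouse 2, and the whole libraries held 2 and 10 Il13 UMIs. The others lay in erythroid cells, 1 of 1424 (0.0702%) and 2 of 3268 (0.0612%), so at 2 months erythroid cells held as many Il13 UMIs as basophils. T cells, another known source of both cytokines, held neither in 444 cells at 2 months, which allows a share of up to 0.676%, nor in 657 cells at 6 months, which allows up to 0.457%. These limits cover detected transcripts only: T cells had medians of 3371.5 and 2811 UMIs, against 7637 and 7881 in basophils, so cells that make either cytokine could have gone unseen. At Leiden resolution 2 a class like type 2 innate lymphoid cells stood apart, with 17 cells at 2 months and 28 at 6 months. In the clustering used here those cells have no class of their own and may lie within the T cell class. The Il4 gene (ENSMUSG00000000869) lies on GRCm38 chromosome 11 from 53612460 to 53618665, and Il13 (ENSMUSG00000020383) lies on the same chromosome from 53631323 to 53634702.

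The background was read from monocytes, which are not known to make Il4. At 2 months 4 of 3533 monocytes (0.113%) had an Il4 UMI at a median of 24536 UMIs per cell, against 7637 in basophils. At 6 months 0 of 2624 did, which allows up to 0.114%, at medians of 28653 and 7881. Erythroid cells, also not known to make Il4, held it in 18 of 1424 cells at 2 months (1.26%) and in 17 of 3268 at 6 months (0.52%), at medians of 42269 and 44020 UMIs. At 2 months 17 of these 18 came from mouse 2 (1.59% of 1070 cells), against 1 of 354 in mouse 1 (0.282%). Within each library the basophil share was above that of all other cells by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over classes (adjusted p = 1.4e-62 and 5.4e-86). Of monocytes 0 of 3533 and 0 of 2624 held Il13, which allows up to 0.0849% and 0.114%. For Il13 the same exact test gave adjusted p = 0.863 at 2 months and 4.1e-09 at 6 months. With cells thinned to 1000 UMIs, and 556 and 393 shallower cells left out, the Il4 share of basophils was 3.52% and 3.23% and 0 and 2 basophils kept an Il13 UMI. In basophils summed per mouse Il4 stood at 20.4 CPM (counts scaled to a common library total) at 2 months and 22.1 at 6 months, a log2 change of 0.12 ± 0.25 (SE, n = 2 mice per time; edgeR adjusted p = 0.802). Leaving out a mouse gave changes between -0.02 and 0.21. By this exact test the other classes above the rest at 2 months were eosinophils (5 of 85 cells, 5.88%, adjusted p = 0.00276), megakaryocytes (11 of 212, 5.19%, adjusted p = 1.6e-05) and the unnamed cluster 13 (7 of 318, 2.20%, adjusted p = 0.0459). At 6 months the corresponding counts were 1 of 61, 4 of 268 and 4 of 385. Megakaryocytes with Il4 were 3 of 70 and 8 of 142 in the mice at 2 months and 4 of 110 and 0 of 158 in those at 6 months. Thinned to 1000 UMIs, 0 of 80 eosinophils, 0 of 208 megakaryocytes, 0 of 318 cells of cluster 13 and 0 of 1424 erythroid cells held Il4 at 2 months, which allows shares of up to 3.75%, 1.44%, 0.943% and 0.211%.

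**Figure D1:**
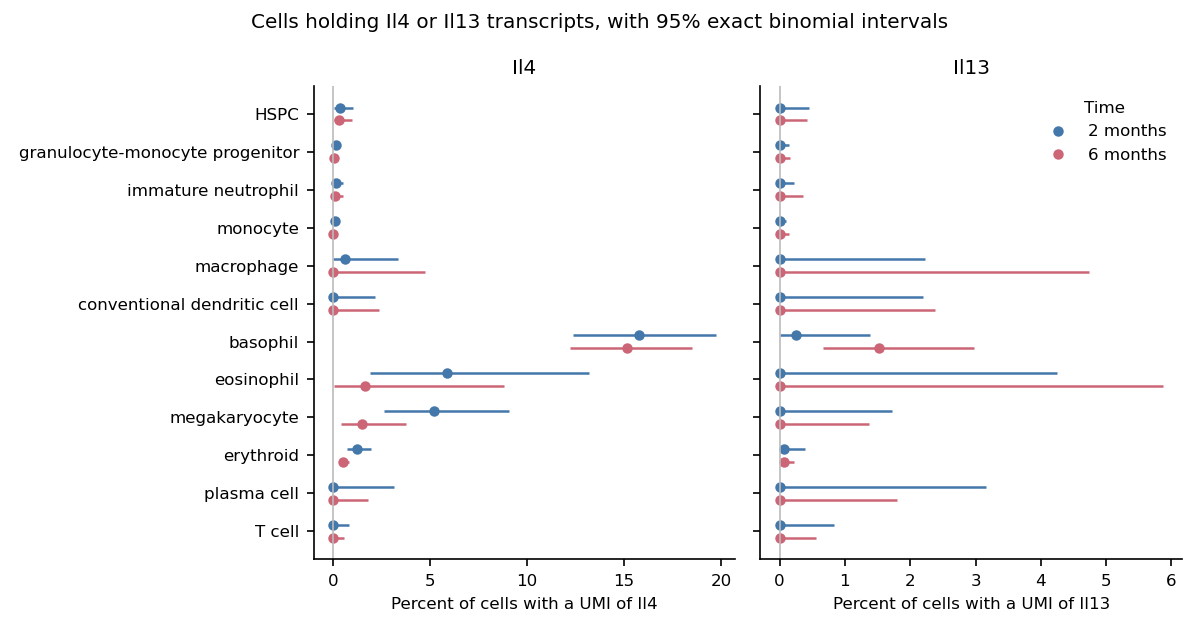
Percent of cells with at least 1 UMI of Il4 (left) or Il13 (right) in each cell class, horizontal axes in percent, at 2 months (blue) and 6 months (red). Points are the shares in a library, with the cells of both mice together, and lines are exact 95% binomial intervals, which cover counting error only. Basophils lie at 15.8% and 15.2% for Il4 and at 0.251% and 1.52% for Il13.

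The receptor chains were found in other cells. Il4ra, the chain shared by the IL-4 and IL-13 receptors, had a UMI in 42.1% and 38.2% of monocytes at 2 and 6 months, in 39.8% and 30.7% of conventional dendritic cells, in 33.9% and 30.8% of HSPC and in 27.3% and 12% of immature neutrophils. In erythroid cells, the background class, the shares were 4.28% and 1.68% at medians of 42269 and 44020 UMIs, above the depth of each of these classes. Thinned to 1000 UMIs, Il4ra remained in 3.26% and 1.41% of monocytes, 8.48% and 3.92% of dendritic cells and 0.14% and 0.0306% of erythroid cells. Il13ra1, the chain that binds IL-13, was held by 31.9% and 39.2% of conventional dendritic cells, 33.0% and 22.2% of plasma cells, 14.6% and 13.2% of macrophages and 7.33% and 5.30% of monocytes, which made up 65.9% and 51.1% of all cells with Il13ra1, against 0.211% and 0.184% of erythroid cells. Thinned, it remained in 7.88% and 7.84% of dendritic cells and in 0 of 1424 and 0 of 3268 erythroid cells, which allows shares of up to 0.211% and 0.0918%. Mice of a time differed: Il4ra was in 30.9% and 56.4% of monocytes and 27.1% and 53.1% of dendritic cells at 2 months. For Il13ra1 the values at 2 months were 22.4% and 42.0% of dendritic cells, 41.1% and 19.0% of plasma cells and 4.91% and 10.4% of monocytes, and at 6 months 32.8% and 17.3% of plasma cells and 18% and 3.85% of macrophages. In counts summed per mouse, Il4ra fell in immature neutrophils by 0.85 ± 0.15 on the log2 scale (edgeR adjusted p = 2.9e-04) and in granulocyte-monocyte progenitors by 0.61 ± 0.16 (adjusted p = 0.0135; SE, n = 2 per time). It did not pass in HSPC (log2 change -0.22 ± 0.23), monocytes (-0.22 ± 0.35) or dendritic cells (-0.14 ± 0.34), where leaving out a mouse could turn the sign (ranges -0.75 to 0.11, -0.65 to 0.40 and -0.52 to 0.37). Il13ra1 stood at 38.6 and 74.4 CPM in dendritic cells and did not pass (edgeR adjusted p = 0.232).

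The second question was whether the shares of the classes among the captured cells changed with time. Mature neutrophils and B cells formed no class, and the labels do not say whether marrow was enriched or sorted before loading, so these shares may not be those of the marrow itself. Erythroid cells averaged 11.5% ± 8.85 of a mouse's cells at 2 months and 24.0% ± 11.2 at 6 months (SD, n = 2). Monocytes averaged 27.6% ± 2.47 and 20.6% ± 3.22, immature neutrophils 12.9% ± 4.73 and 7.86% ± 2.26, granulocyte-monocyte progenitors 20.9% ± 6.34 and 18.2% ± 2.64, and HSPC 6.62% ± 4.41 and 7.52% ± 7.75. Plasma cells stood at 0.892% ± 0.275 and 1.51% ± 0.507, T cells at 3.48% ± 0.128 and 5.37% ± 2.94, basophils at 3.09% ± 1.08 and 4.01% ± 0.494, and megakaryocytes at 1.70% ± 0.932 and 2.05% ± 0.101. Macrophages stood at 1.32% ± 0.925 and 0.626% ± 0.390, conventional dendritic cells at 1.31% ± 0.0575 and 1.30% ± 1.22, and eosinophils at 0.665% ± 0.0480 and 0.5% ± 0.288. In the edgeR quasi-likelihood test on cell numbers 0 classes passed, 0 had an unadjusted p under 0.05, and adjusted p ran from 0.881 to 0.993, with log2 changes of 1.06 ± 0.80 (SE) for erythroid cells and -0.72 ± 0.79 for immature neutrophils. The erythroid change was 0.43 without mouse 1 and 2.19 without mouse 2 of 2 months, and 0.48 without mouse 2 of 6 months. That of neutrophils was -0.28 without mouse 1 of 2 months, -0.45 without mouse 1 of 6 months, -0.12 under the stricter cell filter and -1.30 with the first clustering, before the libraries were balanced. The mice of the times did not overlap for plasma cells, monocytes and immature neutrophils, 3 of the 12 named classes, where chance gives 33.3%. An exact two-sided permutation of 2 mice against 2 cannot go below p = 0.333. Of the megakaryocytes that passed the other filters 32.7% at 2 months and 20.2% at 6 months had no tag and could not be given to a mouse.

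**Figure D2:**
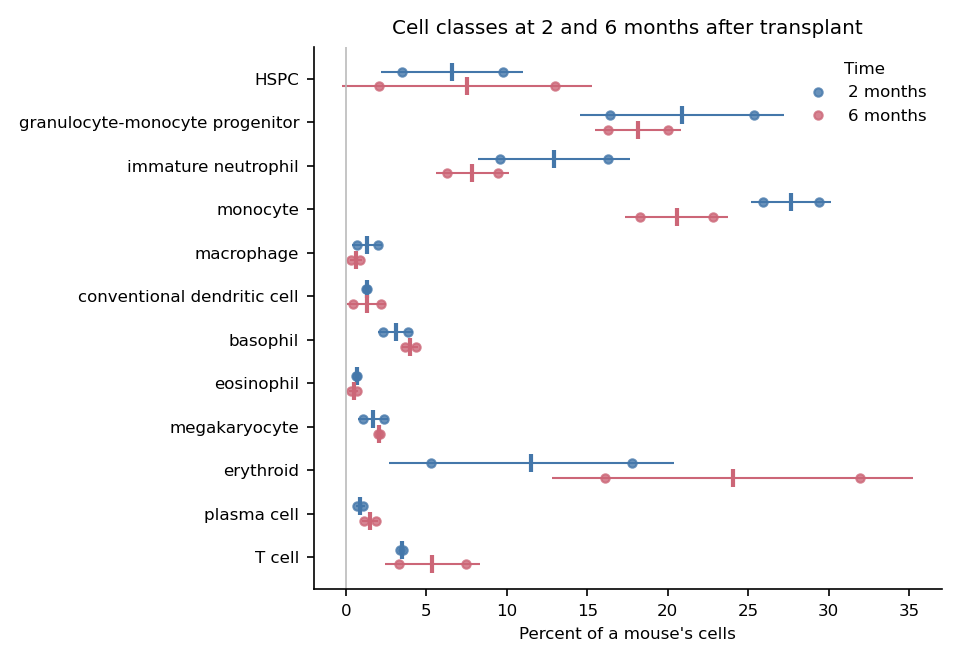
Share of each cell class among a mouse's cells, horizontal axis in percent, at 2 months (blue) and 6 months (red). Points are the 2 mice of a time, ticks their mean and lines ± 1 SD. Erythroid cells span 5.27% to 17.8% at 2 months and 16.1% to 32.0% at 6 months.

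Gene expression was then compared between the times within each class, on counts summed per mouse. Most changed genes lay in the granulocytic line. In granulocyte-monocyte progenitors 2970 genes rose and 2916 fell among 12148 tested, and in immature neutrophils 2782 rose and 2432 fell among 10517. Monocytes had 1579 genes up and 890 down, erythroid cells 956 and 563, HSPC 790 and 338, basophils 785 and 333, T cells 176 and 75, conventional dendritic cells 83 and 31, eosinophils 18 and 10, and plasma cells 5 and 0. These counts are edgeR quasi-likelihood calls with Benjamini-Hochberg adjustment within a class, and every gene-level adjusted p given for a class is from this test. DESeq2 called 4686, 3516, 3044, 2080, 800, 417, 98, 135, 22 and 19 genes in the same classes. Over all classes 57.2% of the 17732 calls were up. With DESeq2 the share of higher calls was 81.6% in place of 70.1% in T cells, 84.9% in place of 70.2% in basophils and 90.9% in place of 64.3% in eosinophils. The groups of mice did not overlap in 75.6% of the genes tested in progenitors and 74.5% in neutrophils, where chance gives 33.3%. In the other named classes this ran from 26.5% in macrophages, below chance, to 64.2% in monocytes.

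**Figure D3:**
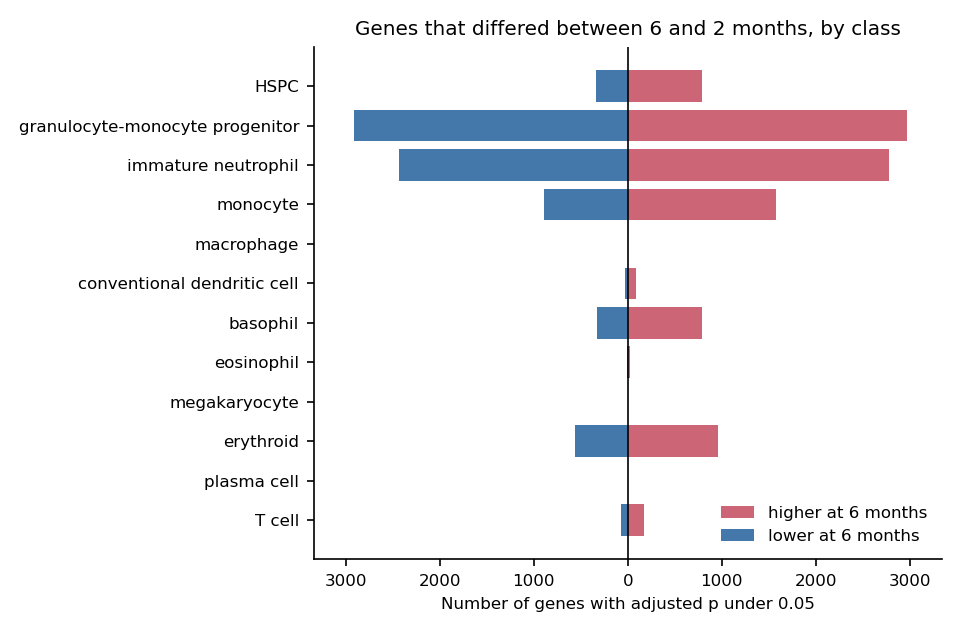
Number of genes with an edgeR adjusted p under 0.05 between 6 and 2 months in each cell class, horizontal axis in genes. Bars to the right are genes higher at 6 months and bars to the left genes lower at 6 months, with the longest bars at 2970 and 2916 genes in granulocyte-monocyte progenitors.

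Time and library were the same split: both mice of a time were captured in 1 library, so the p-values measure the spread between the mice within a library, and a time effect and a library effect cannot be told apart. Many genes moved alike in classes of different lineage. In at least 6 of the 12 classes 362 genes rose and 72 fell, among them the ubiquitin gene Ubb, the RNA polymerase subunit gene Polr2j and the ribosomal protein genes Rplp0, Rpl14 and Rps18, each up in 9 classes, and Sod1 and Hist1h3c, each down in 8. Plasma cell transcripts were among them. Igha, the IgA heavy chain gene (ENSMUSG00000095079, chromosome 12 from 113256204 to 113260236), rose by 1.97 ± 0.13 in HSPC, 1.94 ± 0.10 in progenitors, 1.88 ± 0.15 in monocytes, 2.23 ± 0.24 in erythroid cells and 2.09 ± 0.18 in T cells (log2 ± SE, n = 2 per time). The neutrophil granule transcript Ngp moved the other way, and fell by 1.90 ± 0.15 in HSPC, 1.95 ± 0.20 in monocytes and 2.74 ± 0.30 in basophils. Other granule transcripts did not all follow: Ctsg rose in 7 of the 12 classes and fell in 1, and Lcn2 rose in 3 and fell in 2. Outside the cells that make them, Igha, Igkc and Jchain together averaged 2.34 UMIs per cell at 2 months and 6.61 at 6 months, and Ngp, Camp, S100a8 and S100a9 averaged 18.4 and 11.4. Change also went with gene length. With genes split into 4 equal sets by genomic span, the median log2 change of the shortest set exceeded that of the longest in all 12 classes, by 0.238 to 0.726 (median 0.394). In the 2 splits of the mice that mix the libraries the medians of this difference were 0.0210 and 0.0359.

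**Figure D4:**
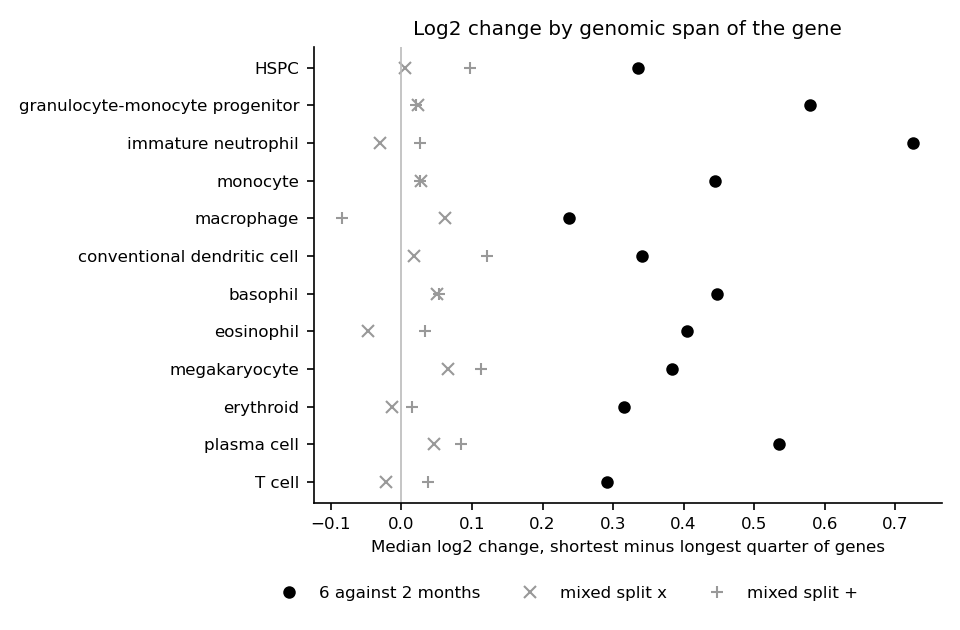
Difference in median log2 change between the shortest and the longest of 4 equal sets of tested genes by genomic span, horizontal axis in log2 units, for each cell class. Black points compare 6 with 2 months and lie between 0.238 and 0.726. Grey crosses are the 2 splits that put 1 mouse of each time in each group, with mouse 1 of both times together (×) or mouse 1 of 2 months with mouse 2 of 6 months (+), and lie between -0.0840 and 0.122.

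Genes of oxidative phosphorylation, which code for subunits of the respiratory chain and ATP synthase, passed upward over all genes in 6 of the 12 classes. In granulocyte-monocyte progenitors 23 of 27 rose and Sdha fell, with 24 up when adjusted over the list alone. In immature neutrophils 25 rose and Sdha fell, and 25 rose over the list alone. Counts up were 18 in monocytes (19 adjusted over the list alone), 12 in erythroid cells (13), 9 in basophils (15) and 5 in HSPC (8). In megakaryocytes, plasma cells and eosinophils 0 members passed over all genes, and 7, 7 and 0 passed adjusted over the list alone. In conventional dendritic cells, macrophages and T cells 0 passed on either count. The ATP synthase gene Atp5c1 (ENSMUSG00000025781, chromosome 2 from 10056030 to 10080510) rose by 1.11 ± 0.08 in neutrophils, 1.0 ± 0.07 in progenitors, 0.67 ± 0.09 in monocytes and 0.55 ± 0.10 in HSPC, and Cyc1 rose by 0.99 ± 0.08, 0.93 ± 0.07 and 0.83 ± 0.12 in the first 3. The list passed camera with a preset correlation in these 9 classes (adjusted p from 2.8e-13 in neutrophils to 0.0019 in HSPC), and in each the adjusted p was 0.982 with an estimated correlation. Within the shortest of the 4 sets of genes it passed camera in progenitors (adjusted p = 7.8e-04), neutrophils (6.7e-04) and monocytes (0.0243), and not in the other 6 named classes, where adjusted p ran from 0.146 in basophils to 0.609 in HSPC. Its call in HSPC also ended without mouse 1 of 2 months (camera adjusted p = 0.0581). With cells thinned to 1000 UMIs the plasma cell call ended and its direction turned (camera adjusted p = 0.913).

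**Figure D5:**
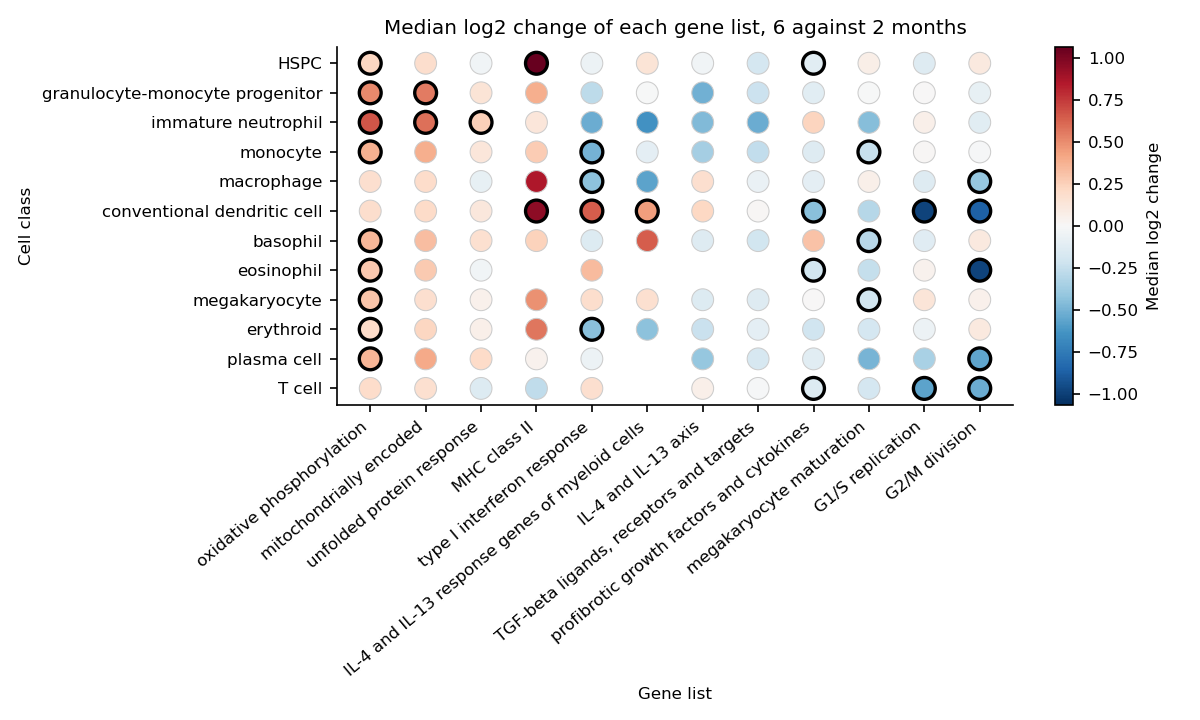
Median log2 change from 2 to 6 months of the tested members of 12 of the 23 fixed gene lists (horizontal axis) in each cell class (vertical axis), by colour in log2 units, red for higher at 6 months. A black rim marks lists that passed camera with a preset correlation at adjusted p under 0.05, and a missing point a list with under 5 tested genes. Oxidative phosphorylation is rimmed in 9 of the 12 classes, with medians from 0.20 in erythroid cells to 0.67 in immature neutrophils.

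In HSPC, the compartment that holds the transplanted stem cells, 1128 genes changed. MHC class II genes, which present antigen, rose: H2-Eb1 by 2.03 ± 0.44 on the log2 scale (edgeR adjusted p = 0.0188), H2-Aa by 1.47 ± 0.38, H2-DMb1 by 1.17 ± 0.15 and H2-Ab1 by 1.16 ± 0.21 (SE, n = 2 per time). That is 4 of 10 members, with 6 adjusted over the list alone, and the list passed camera (adjusted p = 1.4e-04; adjusted p = 0.982 with an estimated correlation). Hmga2, a chromatin protein of self-renewing progenitors, fell by 1.57 ± 0.30 (edgeR adjusted p = 0.0113), and Ubb rose by 1.43 ± 0.09. The list of profibrotic growth factors and cytokines passed in the down direction (adjusted p = 0.0033; adjusted p = 0.982 with an estimated correlation), carried by 2 of 11 members over all genes and over the list alone. These were S100a8 and S100a9, calprotectin genes abundant in neutrophils, which fell by 1.83 ± 0.13 and 1.54 ± 0.12 together with the neutrophil genes Ngp and Camp. Vegfa and Mif did not pass (log2 changes of -0.56 ± 0.37 and 0.20 ± 0.10). Without the top 50 genes of untagged barcodes under 1000 UMIs, which may hold free RNA or damaged cells, the list's adjusted p was 0.910, and without mouse 2 of 2 months it was 0.142. The count of changed genes was 326 without mouse 1 of 6 months, 560 without mouse 2 of 6 months and 741 without mouse 1 of 2 months, 161 with thinned cells and 2437 with the first clustering, before balancing. With that clustering the MHC class II and profibrotic calls ended (camera adjusted p = 0.348 and 0.288).

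In granulocyte-monocyte progenitors the carbonic anhydrase gene Car1 rose by 1.44 ± 0.11, the glutathione transferase gene Gstm5 by 1.54 ± 0.16 and Rbm4b by 1.63 ± 0.10. Hebp1, a heme-binding protein, fell by 1.91 ± 0.09 and the amino acid transporter gene Slc36a1 by 1.72 ± 0.09 (log2 ± SE, n = 2 per time). For these genes edgeR adjusted p ran from 1.1e-04 to 2.6e-04. Car1 is also a fixed erythroid marker and was among the 10 leading genes of erythroid clusters 2 and 7. It rose in eosinophils and the unnamed cluster 13 too, so its rise is not particular to progenitors. Free RNA was weighed for plasma cells and neutrophils only, not for erythroid cells. Jak2 itself fell by 0.51 ± 0.10 (edgeR adjusted p = 0.0042), from 16.1 to 11.3 CPM, as did Jak2 in immature neutrophils, by 0.40 ± 0.12 (adjusted p = 0.0151). Jak2 passed in 2 of 12 classes. Its gene, on chromosome 19 from 29251803 to 29313095, is in the longest set by genomic span. That set starts at 49675 bp in progenitors and 49364 bp in neutrophils, with median log2 changes of -0.27 and -0.32. The fall of Jak2 in neutrophils was therefore within its SE of that median. Whether Jak2 fell beyond other long genes was not tested in either class. Of the 13 mitochondrially encoded genes 7 rose and mt-Co1 fell, with 8 up and 1 down over the list alone, among them mt-Cytb (0.88 ± 0.07) and mt-Co3 (0.74 ± 0.09), and in immature neutrophils 7 rose over all genes and over the list alone. The list passed camera in both classes (adjusted p = 0.0325 and 0.0211), with adjusted p = 0.982 with an estimated correlation. Without the top genes of untagged barcodes its adjusted p was 0.175 and 0.178. It also ended without mouse 2 of 2 months in both (camera adjusted p = 0.0985 and 0.0817) and, in progenitors, without mouse 2 of 6 months (0.0707). The count of changed genes was 3915 without mouse 1 of 2 months. With cells thinned to 1000 UMIs it was 2618, and in neutrophils 1704.

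In immature neutrophils Ctsg, the primary granule protease cathepsin G (ENSMUSG00000040314, chromosome 14 from 56099885 to 56102574), rose by 1.90 ± 0.11, from 536 to 2007 CPM (edgeR adjusted p = 3.8e-08). Ctsg rose in 7 of the 12 classes and fell in conventional dendritic cells, and Sdf2l1 and Pdia6 each rose in 6, so these rises are not particular to neutrophils. The chaperone genes Sdf2l1 and Pdia6 rose by 1.91 ± 0.09 and 1.43 ± 0.09, Manf by 0.93 ± 0.08 and Calr by 0.72 ± 0.08 (log2 ± SE, n = 2 per time). Of 17 genes of the unfolded protein response 10 rose and 2 fell, over all genes and over the list alone, and those that fell were the transcription factor gene Atf4 and Sel1l. The list passed camera (adjusted p = 0.0153; adjusted p = 0.982 with an estimated correlation). Tesc, a calcium-binding protein, fell by 2.77 ± 0.16 and Hebp1 by 1.74 ± 0.12. Balancing the libraries in the clustering was chosen after the data were seen, and with the first, unbalanced clustering the call ended and turned: Calr had a log2 change of -0.04 and the list a camera adjusted p of 0.969, in the other direction. It ended as well without mouse 2 of 2 months (0.0548).

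Cluster 0 made up 50.9% of the monocyte class at 2 months and 59.5% at 6 months. Its 10 leading genes held Cd34, a fixed marker of HSPC, beside Irf8, so the class may hold progenitors too. Monocytes at 6 months were lower in Psap, the precursor of lysosomal saposins, by 1.0 ± 0.18, in Hebp1 by 1.92 ± 0.15 and in Slc36a1 by 1.43 ± 0.11. They were higher in Cenpv by 1.31 ± 0.20 (log2 ± SE, n = 2 per time, edgeR adjusted p from 0.0141 to 0.0194 for these genes). Of 23 tested genes of the megakaryocyte maturation list 4 fell over all genes and over the list alone, and these code for the transcription factors Nfe2 (0.78 ± 0.10), Runx1 (0.55 ± 0.09) and Fli1 (0.45 ± 0.10) and for non-muscle myosin, Myh9 (0.47 ± 0.09), which other blood lineages also use. That list passed camera (adjusted p = 0.0211; adjusted p = 0.982 with an estimated correlation). Of 29 type I interferon response genes Cmpk2 fell by 0.86 ± 0.20 and 0 passed adjusted over the list alone, with a list adjusted p of 0.0244 and an adjusted p of 0.982 with an estimated correlation. The call ended without mouse 1 of 2 months (camera adjusted p = 0.367) and without mouse 2 of 6 months (0.0548). Oas3 and Trim30a had log2 changes of -1.18 ± 0.33 and -0.60 ± 0.17 (edgeR adjusted p = 0.0517 and 0.0548). The 2469 calls in monocytes depended on which mice were kept. With a mouse left out, the spread came only from the pair of the other time. Such fits therefore do not show which mice carried the calls. Under the stricter cell filter 10 genes passed in edgeR, with 3588 at an unadjusted p under 0.05.

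The 10 leading genes of the macrophage class held 5 of its fixed markers. They also held 4 globin genes, Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, fixed markers of erythroid cells, so the class may hold erythroid cells or their RNA. In macrophages 0 of 5018 genes passed in edgeR, 51 had an unadjusted p under 0.05, and DESeq2 called 4. Leaving out a mouse gave 9 genes without mouse 1 of 2 months, 11 without mouse 2 of 2 months, 3 without mouse 1 of 6 months and 0 without mouse 2 of 6 months. The lists of type I interferon response, G2/M division and collagen synthesis passed camera in the down direction (adjusted p = 0.0270, 2.4e-04 and 0.0132), each with adjusted p = 0.982 with an estimated correlation and with 0 members passing over all genes or over the list alone. Each of these calls ended without some mouse. The interferon list had a camera adjusted p of 0.717 without mouse 2 of 6 months, and its members Isg15 and Rsad2 could turn (ranges -1.87 to 0.20 and -0.84 to 0.05). G2/M had 0.277 without mouse 1 of 2 months and 0.972 without mouse 1 of 6 months, and collagen synthesis 0.931 and 0.972 without mouse 2 of 2 or of 6 months. The split of mouse 1 of 2 months and mouse 2 of 6 months against the others called 127 genes by edgeR. That was more than the times did, with 999 at an unadjusted p under 0.05. Those 2 mice held 45 and 26 macrophages at medians of 3010 and 1913 UMIs, and the others 119 and 50 at 7568 and 7097. Igha, Igkc and Jchain together averaged 41.3 and 181 UMIs per macrophage in them, against 1.77 and 4.64. The split therefore also divided the macrophages by depth and by plasma cell transcripts. Fn1, the fibronectin gene of the collagen and matrix list, stood at 45.0 and 4.50 CPM, with a log2 change of -3.38 ± 0.92, and Ube2c of the G2/M list at 200 and 77.0 CPM, -1.35 ± 0.41 (SE, n = 2 per time; both edgeR adjusted p = 0.999).

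In conventional dendritic cells Mgl2, a C-type lectin of type 2 conventional dendritic cells that IL-4 is known to induce in myeloid cells (ENSMUSG00000040950, chromosome 11 from 70130125 to 70137542), rose from 12.3 to 225 CPM, a log2 change of 4.14 ± 0.41 (edgeR adjusted p = 0.00361). The related lectin gene Clec10a rose by 1.49 ± 0.20, and Xcr1, the chemokine receptor of type 1 conventional dendritic cells, fell by 3.54 ± 0.53, from 91.9 to 5.07 CPM (SE, n = 2 per time). Klrd1 and Klrk1, receptor genes best known from natural killer cells, rose by 1.99 ± 0.23 and 2.05 ± 0.36. Nkg7, another gene of those cells, fell by 2.41 ± 0.41. It was also among the 10 leading genes of granulocyte-monocyte progenitor cluster 1, so here it does not mark natural killer cells alone. Ctsg, another leading gene of that cluster, fell in dendritic cells as well. The heme oxygenase gene Hmox1 rose by 1.84 ± 0.36. Of the 6 tested IL-4 and IL-13 response genes of myeloid cells Mgl2 and Clec10a rose, over all genes and over the list alone, and Mrc1 and Klf4 did not pass (0.52 ± 0.30 and 0.33 ± 0.28). That list passed camera (adjusted p = 1.2e-05, and adjusted p = 0.982 with an estimated correlation). It passed in this class alone of the 11 that could be tested, whole marrow included, and whether the classes differ was not tested. Mgl2 is a gene of type 2 and Xcr1 of type 1 dendritic cells, and the class was not split into these. A shift between them was therefore not told apart from a response to either cytokine. Mgl2 was also among the 10 leading genes of granulocyte-monocyte progenitor cluster 4, so in these data it is not particular to dendritic cells. MHC class II genes rose, 6 of 10 and 9 over the list alone, with Cd74 up by 0.95 ± 0.09 and H2-Eb1 by 1.46 ± 0.15; both genes, with H2-Aa and H2-Ab1, were among the markers that named the class. So did 3 of 27 type I interferon response genes (7 over the list alone), Ifitm3 by 1.02 ± 0.11, Zbp1 by 1.33 ± 0.26 and Isg15 by 1.30 ± 0.27. Both lists passed camera (adjusted p = 1.2e-14 and 1.2e-05), each with adjusted p = 0.982 with an estimated correlation, and the interferon call ended without mouse 2 of 2 months (0.0821).

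Cell cycle genes moved the other way in the same dendritic cells. Of 21 G2/M genes 2 fell, Top2a by 1.22 ± 0.21 and Ube2c by 0.84 ± 0.17, and 16 fell adjusted over the list alone, and of 18 G1/S genes Mcm5 fell by 1.69 ± 0.32 and 11 fell over the list alone (log2 ± SE, n = 2 per time). The lists passed camera (adjusted p = 1.2e-14 and 8.0e-08), with adjusted p = 0.982 with an estimated correlation. The immediate early and stress list passed upward (adjusted p = 0.0029; adjusted p = 0.982 with an estimated correlation) with 0 of 19 members over all genes and 8 over the list alone, and with thinned cells its direction turned (adjusted p = 0.782). S100a8, S100a9 and Camp, neutrophil transcripts, fell with log2 changes of -3.79 ± 0.50, -3.31 ± 0.58 and -4.04 ± 0.77, and the profibrotic list passed downward on S100a8 and S100a9 (2 of 9 members, 3 over the list alone; adjusted p = 0.0093, and adjusted p = 0.982 with an estimated correlation). Without the top genes of untagged barcodes its adjusted p was 0.763, without mouse 2 of 2 months 0.272 and without mouse 2 of 6 months 0.0533, and with Scrublet doublets kept Camp and S100a9 had log2 changes of 0.97 and 0.74. The class held 85 and 81 cells at 2 months and 120 and 33 at 6 months. The 114 changed genes became 261 without mouse 1 of 2 months, 658 without mouse 2 of 2 months, 54 without mouse 1 of 6 months and 31 without mouse 2 of 6 months, 33 with Scrublet doublets kept and 24 with thinned cells.

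Basophils had 1118 changed genes. Prg2, major basic protein, which is best known from eosinophils (ENSMUSG00000027073, chromosome 2 from 84980461 to 84983632), rose from 15.4 to 212 CPM, a log2 change of 3.77 ± 0.28 (edgeR adjusted p = 4.5e-09). The chemokine gene Ccl6 rose by 1.63 ± 0.13 and S100a6 by 1.49 ± 0.48, and Ltf, Ly6c2 and Camp, transcripts of neutrophils and monocytes, fell by 4.84 ± 0.80, 1.91 ± 0.20 and 2.20 ± 0.21 (SE, n = 2 per time). Transcription factor genes shared with the megakaryocyte list fell: Gata2, which basophils need, by 0.44 ± 0.12, Runx1 by 0.50 ± 0.13, Tal1 by 0.71 ± 0.19 and Nfe2 by 0.54 ± 0.16. In all 5 of 15 members of that list fell, over all genes and over the list alone (camera adjusted p = 0.0332; adjusted p = 0.982 with an estimated correlation), a call that ended without mouse 1 of 2 months (0.0996) or of 6 months (0.318). The count of changed genes was 650 without mouse 1 of 6 months and 556 without mouse 2, 649 at the finer clustering, 417 by DESeq2 and 112 with thinned cells.

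Eosinophils had 28 changed genes. Among G2/M genes Mki67 and Tpx2 fell by 1.09 ± 0.23 and 1.62 ± 0.35 (log2 ± SE, n = 2 per time), 2 of 20 members over all genes and 14 over the list alone, and the list passed camera (adjusted p = 1.2e-14; adjusted p = 0.982 with an estimated correlation). Hebp1 fell by 3.86 ± 0.68, and Car1, a fixed marker of erythroid cells that also rose in progenitors, rose by 1.5 ± 0.32. The profibrotic list again passed downward on S100a8 and S100a9, 2 of 5 members over all genes and over the list alone, which fell by 2.32 ± 0.38 and 1.88 ± 0.33 beside Ngp and Camp (adjusted p = 0.0054; adjusted p = 0.982 with an estimated correlation). Only 22 to 47 cells per mouse stood behind these values, and the count was 16 and 59 without mouse 1 or 2 of 2 months and 114 and 159 without mouse 1 or 2 of 6 months.

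In T cells Gzmk, a granzyme of cytotoxic T cells (ENSMUSG00000042385, chromosome 13 from 113171630 to 113180965), rose by 2.48 ± 0.52 (edgeR adjusted p = 0.0206), the chemokine gene Ccl5 by 1.84 ± 0.19 and Nkg7 by 0.86 ± 0.19 (log2 ± SE, n = 2 per time), 3 of 14 genes of the type 1 and cytotoxic list, with 6 over the list alone. Foxp3, the factor that defines regulatory T cells, rose by 1.01 ± 0.21, Tnfrsf18 by 1.04 ± 0.25 and Capg by 1.65 ± 0.25, 3 of 9 regulatory genes and 4 over the list alone. Ier3 and Nfkbia rose by 2.09 ± 0.44 and 0.74 ± 0.18, 2 of 12 NF-kB response genes and 4 over the list alone. Of 10 naive T cell genes Satb1 fell by 1.02 ± 0.22, Il7r, the IL-7 receptor gene that memory cells also hold, rose by 1.01 ± 0.21, and 6 fell and 1 rose over the list alone. The cytotoxic, regulatory and NF-kB lists passed camera upward (adjusted p = 5.8e-05, 0.0019 and 0.0074) and the naive list downward (0.0058), each with adjusted p = 0.982 with an estimated correlation. The class is a mix of T cells. At Leiden resolution 2 its cluster with Tnfrsf4 and Foxp3 in the lead held 123 cells at 2 months and 266 at 6 months. The cluster with Lef1, Tcf7 and Ccr7 held 133 and 76, and that with Ccl5 176 and 295, untagged cells included. A shift between such subsets was not told apart from a change within cells. Of 19 G1/S genes 0 passed over all genes and 11 fell over the list alone, with Pcna at -0.63 ± 0.16 (adjusted p = 0.0507), and of 21 G2/M genes 0 passed over all genes and 2 fell over the list alone (camera adjusted p = 1.1e-04 and 7.3e-04, each with adjusted p = 0.982 with an estimated correlation). Several of these calls ended or turned with a mouse left out, which does not show which mice carried them. Without mouse 2 of 2 months G2/M turned (camera adjusted p = 0.807). Without mouse 1 of 2 months the cytotoxic, NF-kB and naive lists had 0.0819, 0.0723 and 0.0996, and without mouse 1 of 6 months the regulatory, NF-kB and naive lists 0.0528, 0.185 and 0.782. The stricter cell filter ended the G1/S, G2/M, NF-kB and regulatory calls (camera adjusted p = 0.679, 0.783, 0.991 and 0.312). The profibrotic list passed downward on S100a8, S100a9 and Lcn2 (3 of 9 over all genes and over the list alone), which fell by 1.88 ± 0.16, 1.5 ± 0.17 and 1.67 ± 0.34 beside Ngp, and without the top genes of untagged barcodes its adjusted p was 0.706 (2.4e-04 with them, and adjusted p = 0.982 with an estimated correlation). It was 0.0932 without mouse 1 of 2 months and 0.271 without mouse 2 of 6 months. The 251 changed genes became 116 and 115 without mouse 1 or 2 of 2 months, 509 without mouse 2 of 6 months, 98 by DESeq2, 47 under the stricter cell filter and 95 with thinned cells.

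Erythroid cells had 1519 changed genes. Sod1, superoxide dismutase, fell by 1.08 ± 0.09 from 346 to 164 CPM, Srp54a fell by 1.21 ± 0.14, and Ubb rose by 1.2 ± 0.14 (log2 ± SE, n = 2 per time; adjusted p from 0.0122 to 0.0147). Of 27 type I interferon response genes 3 fell over all genes and over the list alone, Cmpk2 by 0.77 ± 0.15, Usp18 by 1.37 ± 0.29 and Ifi44 by 3.08 ± 0.70, the last at 1.30 and 0.174 CPM (camera adjusted p = 0.0058; adjusted p = 0.982 with an estimated correlation), a call that ended without mouse 2 of 6 months (0.501). The count depended on which mice were kept. With a mouse left out, the spread came only from the pair of the other time, so such fits do not show which mice carried the calls. DESeq2 on all 4 mice called 2080. Under the stricter cell filter 19 genes passed.

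Megakaryocytes, the cells most closely tied to marrow fibrosis in these diseases, had 0 changed genes among 10628 in edgeR, 2177 at an unadjusted p under 0.05 and 161 by DESeq2, and 885 passed in edgeR with no filter on low counts. The members of the megakaryocyte maturation list with the smallest p stood lower at 6 months in both mice without passing. These were the integrin genes Itgb3 at 594 against 1179 CPM (log2 change -0.99 ± 0.21; ENSMUSG00000020689, chromosome 11 from 104608000 to 104670476) and Itga2b at 1257 against 1926 CPM (-0.62 ± 0.17), and Vwf at 378 against 627 CPM (-0.73 ± 0.20; SE, n = 2 per time, adjusted p from 0.149 to 0.157). Other platelet receptor genes of the list stood at -0.13 ± 0.21 (Gp1ba), -0.01 ± 0.32 (Gp9), 0.07 ± 0.22 (Gp5) and -0.83 ± 0.34 (Gp6). The list passed camera downward with a median of -0.20 over 26 members, of which 6 were above 0 and 0 passed over all genes or over the list alone (adjusted p = 0.0077; adjusted p = 0.982 with an estimated correlation), and the call ended without mouse 1 of 2 months (0.260) or mouse 2 of 6 months (0.234). Genes of this list also named the class. Jak2 had a log2 change of -0.56 ± 0.15 (edgeR adjusted p = 0.154) and Tgfb1, the profibrotic cytokine, stood at 654 and 625 CPM (adjusted p = 0.832). Leaving out a mouse gave 0, 79, 4 and 3 genes, for mice 1 and 2 of 2 months and mice 1 and 2 of 6 months.

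In plasma cells 5 genes rose and 0 fell, named after their values were seen: Iglc3, a light chain constant gene (2.83 ± 0.27), the variable segments Igkv3-7, Ighv1-9 and Ighv5-4, and AY036118 (2.05 ± 0.22; log2 ± SE, n = 2 per time). Variable segments follow which clones a mouse holds. Igkv3-7 and Ighv5-4 had 0 CPM in both mice of 2 months. Of 16 G2/M genes 0 passed over all genes or over the list alone, with Cenpf at -1.0 ± 0.30, and the list passed camera downward (adjusted p = 0.0221; adjusted p = 0.982 with an estimated correlation), a call that ended without mouse 2 of 2 months (0.25) or mouse 1 of 6 months (0.224). At an unadjusted p under 0.05 there were 952 genes, DESeq2 called 19, and edgeR called 228 with no filter on low counts, 13 and 61 without mouse 1 or 2 of 2 months and 182 and 179 without mouse 1 or 2 of 6 months.

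In whole marrow, here the sum of all cells given to a mouse, where composition enters, 2 of 15594 genes passed in edgeR, Lyrm7, a mitochondrial assembly factor (3.03 ± 0.16), and Iglc3 (3.42 ± 0.19; log2 ± SE, n = 2 per time; both adjusted p = 0.0493), named after their values were seen. DESeq2 called 2588, and 4102 had an unadjusted p under 0.05 in edgeR. Without any 1 of the 4 mice 0 genes passed in edgeR. Oxidative phosphorylation passed camera upward, with 0 of 27 members over all genes and 15 over the list alone (adjusted p = 1.9e-06; adjusted p = 0.982 with an estimated correlation), and so did heme and globin synthesis, with 0 of 20 members over all genes or over the list alone (adjusted p = 0.0174; adjusted p = 0.982 with an estimated correlation). Alad, an enzyme of heme synthesis, had a log2 change of 1.03 ± 0.32 (edgeR adjusted p = 0.134), and the list's direction turned without mouse 1 of 2 months (camera adjusted p = 0.737) and its call ended without mouse 2 of 6 months (0.444).

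The lists of the IL-4 and IL-13 axis, TGF-beta and JAK-STAT passed in no class. For the IL-4 and IL-13 axis, made of the cytokines, receptor chains and their kinases, the smallest camera adjusted p was 0.0547, in immature neutrophils, where 6 of 8 tested members fell over all genes and over the list alone. In granulocyte-monocyte progenitors 5 of 9 fell on both counts (camera adjusted p = 0.0942). The TGF-beta list had its smallest adjusted p, 0.0786, in monocytes, and the list of JAK-STAT feedback genes and targets, 0.247, in conventional dendritic cells. Camera with an estimated correlation called 0 of 263 list and class pairs, with 2 at an unadjusted p under 0.05. The preset correlation called 49 and fry 1, and 0 pairs were called by both of these in the same direction. Tgfb1, Tgfbr1 and Tgfbr2 passed in none of the 12, 11 and 11 classes that could test them, with smallest edgeR adjusted p of 0.2, 0.0718 and 0.129. The T cell lists of exhaustion and of helper type 2 had smallest adjusted p of 0.0811 and 0.765.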

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

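The differences between classes and the tests on doublets with neutrophils, on a difference between the libraries and on Il4 in megakaryocytes were chosen after the result was seen. Those on free RNA of plasma cells and neutrophils, doublets with plasma cells, gene length and depth were set before their results were seen.

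Of the genes called up in 1 class and down in another, 9 were fitted for the difference itself, in edgeR over both classes with the mouse as a block. They were picked for opposite calls, so a difference was all but fixed beforehand and these values are sizes, not tests. Tesc rose in T cells and fell in granulocyte-monocyte progenitors, a difference of 4.35 ± 0.37 (log2 ± SE, n = 2 mice per time). Immature neutrophils and conventional dendritic cells differed for Camp (4.06 ± 0.57), S100a9 (3.70 ± 0.41) and Ctsg (3.65 ± 0.30), which rose in neutrophils, and for Hmox1 (2.88 ± 0.54), which rose in dendritic cells. Nkg7 differed between T cells and dendritic cells (3.35 ± 0.42), Lcn2 between progenitors and T cells (2.71 ± 0.36), S100a6 between basophils and erythroid cells (2.81 ± 0.63) and Ube2c between progenitors and dendritic cells (1.14 ± 0.17). With Scrublet doublets kept, the log2 changes of Camp and S100a9 in dendritic cells were positive (0.97 and 0.74).

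Signals also lay in cells and tags outside the comparisons. Megakaryocytes without a tag were 32.7% of that class at 2 months and 20.2% at 6 months, against 0.726% and 1.13% of HSPC. Tags of the other library were counted as well, with 6753 counts of HTO_M0303 at 2 months and 34864 of HTO_M0302 at 6 months.

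Plasma cell transcripts were higher and the neutrophil transcripts Ngp, Camp, S100a8 and S100a9 lower at 6 months in classes that do not make them. Doublets with plasma cells are argued against, since the 1% of cells with most Igha, Igkc and Jchain held 19.1% of those UMIs at 6 months. For the neutrophil transcripts that 1% held 37.2% at 2 months and 64.4% at 6 months, so doublets with neutrophils stay open for those UMIs. They are argued against only for the middle cell of a class, whose UMIs changed by a median ratio of 0.310 (from 0.222 to 0.4). Free RNA of plasma cells is a candidate explanation, since the mice of the 6 month library held alike amounts per cell (median ratio of 1.0035 over 12 classes, from 0.851 to 39.1) while 1.15% and 1.87% of their cells were plasma cells. Free RNA of neutrophils is another (median ratio of 0.989 over 10 classes at 2 months, from 0.211 to 6.39, with 16.3% and 9.57% neutrophils). Classes far from 1, such as macrophages and dendritic cells, are not covered by this, and a change of plasma cells and neutrophils with time stays open. Their shares did not pass (log2 changes of 0.76 ± 0.81 and -0.72 ± 0.79, SE, edgeR adjusted p = 0.881), which does not show that they were unchanged.

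Many genes moved in the same direction in at least 6 of the 12 classes, with a median correlation of log2 changes between classes of 0.516, against 0.0892 and 0.150 in the splits that mix the libraries. Thinned cells kept 98.6% of the median change of the shared genes. Thinning keeps the expected share of each gene in a cell's UMIs, so this result was all but fixed beforehand. It does not decide whether depth per cell plays a part. A bias by gene length may be part of the shared movement: the shortest genes exceeded the longest by a median of 0.394. In progenitors the times differed in 5886 genes by edgeR and both splits that mix the libraries in 0 (33 and 76 at unadjusted p under 0.05), which both a library difference and a change with time predict. This does not hold in every class. A mixed split called 127 genes in macrophages, where the times gave 0 (51 at unadjusted p under 0.05, and 4 by DESeq2). In plasma cells mixed splits called 9 and 6 against 5. The macrophage split also divided that class by depth, with medians of 3010 and 1913 UMIs per cell against 7568 and 7097. Its 127 calls therefore do not weigh between a library difference and a change with time. A library difference and a change with time cannot be told apart, because each time is 1 library.

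Il4 in megakaryocytes lay in cluster 21, where 14 of 149 cells held 38 UMIs (9.40%), up to 12 in a cell, against 1 of 326 in cluster 17, which had more UMIs per cell (medians of 20903 and 44832). Doublets with basophils are argued against by a median of 1 basophil UMI in the Il4 cells of cluster 21, against 371 in basophils with Il4. Free RNA is argued against by the difference between the clusters (Fisher's exact test, p = 6.3e-07). Expression of Il4 by some of these cells may remain as a hypothesis, found and tested on the same cells. Mouse 2 of 2 months held 28 of the 38 UMIs, and mouse 2 of 6 months 0 in 38 cells; without the former 7 of 102 cells held 10 UMIs, against 0 of 231 in cluster 17 (exact p = 2.2e-04).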

How the results depend on the processing

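Balancing the libraries in the clustering used throughout was chosen after seeing the data, and the first, unbalanced clustering was therefore added as an alternative. Totals without cluster 3 and the shortest genes by span were also chosen after seeing the data. Of the named genes' values under settings that kept all mice, 2193 held their direction and side of the threshold, 193 no longer passed, 127 newly passed and 11 changed sign. For lists these counts were 278, 158 and 3 (same, lost, reversed). The cause was not tested where values moved, except that thinned cells and the stricter filter hold fewer counts or cells. Eosinophils, macrophages and cluster 3 had too few cells for gene tests under the stricter filter, with 7, 4 and 16 in a mouse. No paired analysis was possible because the 2 times share no mouse and tag order carries no pairing.

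Changed genes by DESeq2 numbered 417 in basophils, 4 in macrophages, 161 in megakaryocytes, 19 in plasma cells, 98 in T cells and 2588 in whole marrow. With no filter on low counts edgeR called 419 in dendritic cells, 111 in eosinophils, 3087 in erythroid cells, 24 in macrophages, 885 in megakaryocytes, 228 in plasma cells, 556 in T cells and 1689 in whole marrow. Relative log expression gave 0 in whole marrow by edgeR. At Leiden resolution 2 basophils had 649 and eosinophils 116. The stricter hashtag call gave 88 in eosinophils and 0 in whole marrow. The stricter cell filter left 5929 cells given to 1 mouse at 6 months, a dendritic cell share change of 0.33, and 19 genes in erythroid cells, 10 in monocytes, 8 in plasma cells, 47 in T cells and 0 in whole marrow. With Scrublet doublets kept the dendritic cell share changed by 0.042, its genes numbered 33 and those of plasma cells 2, and Camp and S100a9 in dendritic cells stood at 0.97 and 0.74. TMM scaling of cell numbers gave share changes of 0.21 in dendritic cells and 0.16 in granulocyte-monocyte progenitors.

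Thinned to at most 1000 UMIs, edgeR called 112 genes in basophils, 24 in dendritic cells, 13 in eosinophils, 354 in erythroid cells, 2618 in granulocyte-monocyte progenitors, 161 in HSPC, 1704 in neutrophils, 1419 in monocytes, 95 in T cells and 653 in whole marrow. There 31 list and class pairs passed, the immediate early list in dendritic cells had a camera adjusted p of 0.782 and oxidative phosphorylation in plasma cells 0.913, both turned, and Atp5b (-0.15) and Atp5d (-0.73) in plasma cells, Mif in eosinophils (-0.23) and Mrc1 in dendritic cells (-0.014) changed sign. In cells thinned for the shares at 2 months Il13 was in 0% of basophils and erythroid cells, Il4 in 0% of eosinophils, erythroid cells and megakaryocytes, and Il4ra in 5.35% of T cells and 2.13% of macrophages, and at 6 months Il4ra was in 0% of megakaryocytes and 1% of plasma cells, each now on the other side of the remaining cells. Camera with an estimated correlation passed 0 pairs (2 at unadjusted p under 0.05), fry 1 and the shortest genes 19. Of the 49 pairs that passed camera with the preset correlation, fry passed 0 in the same direction. With the first clustering, without balancing, HSPC had 2437 changed genes, the unfolded protein response in neutrophils had a camera adjusted p of 0.969, and log2 changes were -0.042 for Calr in neutrophils, 2.25 for Camp in progenitors, -0.30 for Klf4 in dendritic cells, -0.0074 for Mif in eosinophils and 0.61 for Vegfa in HSPC.

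Leaving out each mouse, with the lone mouse assumed to vary like those of the other time, gave edgeR counts of 326 to 1357 in HSPC, 115 to 509 in T cells, 556 to 1440 in basophils, 31 to 658 in dendritic cells, 16 to 159 in eosinophils, 0 to 3470 in erythroid cells, 3915 to 6267 in granulocyte-monocyte progenitors, 3666 to 5221 in neutrophils, 0 to 11 in macrophages, 0 to 79 in megakaryocytes, 8 to 2429 in monocytes, 13 to 182 in plasma cells and 0 in whole marrow. Of 49 list and class pairs called, 26 ended without 1 of the mice. The camera adjusted p ran from 1.7e-16 to 0.807 for G2/M genes in T cells and from 4.5e-09 to 0.737 for heme synthesis in whole marrow. Log2 changes ran from -0.021 to 0.21 for Il4 in basophils, -0.75 to 0.11, -0.52 to 0.37 and -0.65 to 0.40 for Il4ra in HSPC, dendritic cells and monocytes, -1.87 to 0.20 for Isg15 in macrophages and -0.84 to 0.049 for Rsad2 in macrophages, and -0.081 to 0.72 for Klf4 in dendritic cells. Share changes ran from 0.43 to 2.19 for erythroid cells, -1.05 to -0.28 for immature neutrophils, -1.69 to 1.10 for HSPC, -0.084 to 1.10 for T cells, -1.55 to 0.73 for dendritic cells, -1.16 to 0.079 for eosinophils, -0.48 to 0.14 for granulocyte-monocyte progenitors and -0.20 to 0.98 for megakaryocytes.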

Other observations

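Cluster 13 met no naming rule but held the progenitor genes Meis1 and Sox4 among its leading genes, beside Apoe, Angpt1 and F2r, in 715 cells. At 6 months it was higher in Car1, an early erythroid gene, by 1.66 ± 0.18, in the heme enzymes Alad (0.58 ± 0.14) and Urod (0.59 ± 0.17) and in H2-DMb1 (1.52 ± 0.23; log2 ± SE, n = 2 mice per time). It was lower in S1pr1 (0.91 ± 0.22) and Foxp1 (0.40 ± 0.11), genes of the naive T cell list that progenitors also use. Over all genes 3 of 15 heme genes rose (3 adjusted over the list alone), 10 of 27 genes of oxidative phosphorylation rose (13), 3 of 6 naive T cell genes fell (4), and of 11 profibrotic genes S100a8, S100a9 and Lcn2 fell and Mif rose, on both counts. These lists passed camera (adjusted p = 0.0054, 2.0e-05, 0.0074 and 0.0054), each with adjusted p = 0.982 with an estimated correlation, and the profibrotic list had 0.756 without the top genes of untagged barcodes under 1000 UMIs and 0.306 without mouse 1 of 6 months. In all 1013 genes passed in edgeR and 452 by DESeq2, with 242, 357, 729 and 1437 in edgeR without mouse 1 or 2 of 2 months or mouse 1 or 2 of 6 months.

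Cluster 3 held cells of low depth, with medians of 778 and 656.5 UMIs at 2 and 6 months, and 63.3% and 28.1% of them had no tag. S100a8 and S100a9 fell there by 1.28 ± 0.23 and 1.10 ± 0.22 and Cox5b rose by 1.18 ± 0.23 (log2 ± SE, n = 2 mice per time). Camera passed oxidative phosphorylation upward (1 of 27 members over all genes and over the list alone), heme synthesis upward (0 of 14; 5), the profibrotic list downward (2 of 7; 4) and the unfolded protein response downward (0 of 15; 2), with adjusted p = 2.4e-04, 0.0093, 0.0091 and 0.0144, each with adjusted p = 0.982 with an estimated correlation. Without mouse 2 of 6 months the heme and profibrotic lists had camera adjusted p of 0.0561 and 0.0697, and the unfolded protein response had 0.183 and 0.208 without mouse 1 of 2 or of 6 months. In edgeR 59 genes passed, 37.3% of them up, and in DESeq2 63, 66.7% of them up. The edgeR count was 16, 48, 1031 and 627 without mouse 1 or 2 of 2 months or mouse 1 or 2 of 6 months.

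Among the genes shared by at least 6 classes some moved far in both mice of a time. Atp9a had 394 and 809 UMIs at 2 months and 26 and 38 at 6 months, and Lyrm7 had 326 and 418 against 2701 and 3813. Prkcz had 95 and 96 against 451 and 558. These genes were chosen after their values were seen. At Leiden resolution 2 a class like type 2 innate lymphoid cells appeared, with 8 cells in the mouse that had fewest, too few to test.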
